A study of Mus musculus with 54 samples.

How the data were processed

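The study asked whether removing Xist, the noncoding RNA that silences an X chromosome, changes gene expression in cloned mouse embryos. RNA of single blastocysts cultured for 96 h was amplified linearly in successive rounds, labelled with Cy3 and hybridised to one-colour Agilent arrays, per the labels' protocols. Each of the 54 arrays held 1 embryo or 1 clone. Groups were taken from the labels. They were 6 female and 6 male embryos made by in vitro fertilisation (IVF), 7 cumulus cell clones, 3 cumulus clones treated with trichostatin A (TSA, a histone deacetylase inhibitor), 5 clones of Xist-KO cumulus cells, 4 Sertoli cell clones, 4 clones of Xist-KO Sertoli cells and 8 fibroblast clones, all described as BDF1, a cross of C57BL/6 and DBA/2. A further 3 clones (2 male, 1 female) were made from donor nuclei of 4-cell embryos. The cross of C57BL/6 and 129 (B6x129) gave 3 male IVF embryos, 1 female IVF embryo and 4 Sertoli clones. The series text describes the replicates as made with different donor cells. The p-values therefore measure the spread between these embryos, and their number limits the precision.

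The scanner tables that the authors deposited hold an intensity per spot on a linear scale, background-corrected by the scanner's Feature Extraction software, per the file headers. Software version 9.5.3.1 read 49 arrays and version 10.5.1.1 read 5, the latter on a second scanner. The authors also deposited a value table whose entries are a ratio with no stated scale. Set against the scanner values, each entry equalled the processed signal divided by the median of its array and then by the median of its probe. Over 9807 bright probes this left a residual SD of at most 0.0011 on the log2 scale. The array scale matched the array median to within a range of 0.103 log2. Values stop at a floor of 0.01, where 7.39% of them lie. Column medians ran from 0.598 to 1.129. The direction is that of the signal, and why the offsets differ by 0.103 stays unknown.

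The processed signal of spots of the same probe was averaged without spots marked as non-uniform or as population outliers (103 to 614 per array). It was divided by the 75th percentile of the array, floored at 0.01 of that value and put on the log2 scale. All levels are on this scale. Of 41174 probes, 30020 were well above background on at least a 0.5 share of the arrays of at least 1 group of 3 or more. A gene with several probes took the probe with the highest mean, and where other probes of a named gene disagreed in sign this is said. This left 20414 genes, 559 of them X-linked, 15453 autosomal and 12 Y-linked. Names came from the GRCm38.p6 gene table, by accession for 23082 probes, by symbol for 6582 and by synonym for 3073, and 8437 probes kept the array's own name. The table served only for names, chromosomes and gene order. It and the array files named the same chromosome for 99.77% of 32369 probes. A missing value, from spots left out, affected 1319 genes (0.32% of values), and 82 genes were left out of the list tests for it.

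Each array had 51.2 to 61.1% of its probes well above background and at most 3 saturated. Where a probe was not well above background on any array of a group, the difference is given as "at least N-fold". This bound is the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal.

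All 15 comparisons came from a single limma fit over every array with 1 term per group, with Benjamini-Hochberg adjustment in each comparison at 0.05. The median residual SD was 0.65 log2. The X index of an embryo is the median level of its X-linked genes minus that of its autosomal genes. The X shift is the difference of group means of this index. It was tested two-sided, by exact permutation, or by a permutation test with 100000 resamples of residuals for differences between differences, and adjusted over the 15 comparisons. The named genes were Xist, the 8 largest rises and falls (4 for the later comparisons) and the 6 X-linked genes with the smallest p. From each list came up to 4 members that passed and 2 that did not, and names without a gene symbol were left out. The text gives a selection of these, and genes outside the rule were chosen after their values were seen, as is said there. A fixed set of 27 gene lists (732 genes, 625 measured) was tested with camera at a preset correlation of 0.01. Of 405 tests 85 passed, 74 passed with fry and 12 passed with the correlation estimated. The lists covered the X-inactivation centre, genes known to escape X inactivation, the Xlr, Mage and Rhox families, Y-linked, paternally and maternally expressed imprinted genes, pluripotency, trophectoderm, primitive endoderm, placental trophoblast, cumulus, Sertoli and fibroblast markers, zygotic genome activation, germline genes, oocyte transcripts, chromatin modifiers, p53 targets, heat shock, glycolysis, oxidative phosphorylation, cholesterol synthesis, cell cycle, signalling and housekeeping genes. Groups, comparisons, lists, the rule for named genes and most alternatives were fixed before the data were examined.

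The arrays lay on 18 slides scanned on 11 days. Scans without a gap of more than 60 days on the same scanner formed 6 campaigns. Campaigns 1 and 5 held more than 1 group in full or in part. They gave blocked and within-campaign values for cumulus, TSA, fibroblast, 4-cell and IVF comparisons. Campaign 3 held Sertoli and Xist-KO Sertoli clones on a slide each, so that slide and group cannot be told apart there. Other batches were tried as a random block for slide, with a consensus correlation of 0.139.

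Alternatives were quantile normalization, normexp (offset 50) with quantile normalization, centring on the median, the value table, other filters and floors, the mean of probes, only the arrays compared, array weights, slide, campaign and replicate blocks, and leaving out each array. The background correction used the median spot signal because the files held no mean signal. Overlaps between comparisons with shared controls were set against simulated groups without effect. Of 20414 simulated genes, 67, 67 and 66 were changed by 1, 2 and 3 log2. Of these, 19, 55 and 51 were recovered for cumulus clones with 8 false calls, and 10, 49 and 53 for Sertoli clones with 6, both against IVF. Xist-KO against plain Sertoli clones gave 9, 34 and 54 with 7, and TSA 8, 42 and 48 with 4. This does not bound false calls on real arrays. Computation used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.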

Results

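Gene expression was measured in 54 single mouse blastocysts, 1 per array. They were IVF embryos of either sex, clones of cumulus cells, Sertoli cells and fibroblasts, clones of cumulus or Sertoli cells in which Xist had been deleted (Xist-KO), cumulus clones treated with TSA, and clones of 4-cell embryo nuclei. A second cross, B6x129, supplied IVF embryos and Sertoli clones. Between 51.2 and 61.1% of the probes of an array were well above background. No array duplicated another: the highest correlation between arrays was 0.975, and the lowest within a group was 0.897.

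Xist, the RNA that coats and silences an X chromosome, was looked at first, because deleting it was the intervention. Its level, as log2 relative to the 75th percentile of the array, was -6.05 ± 1.18 (SD, n = 4) in Xist-KO Sertoli clones, where 3 of 4 embryos lay at the floor of -6.64 and the fourth at -4.28. Sertoli clones with an intact gene, which like all male embryos carry a single X, stood at 2.65 ± 0.56 (n = 4). Xist-KO cumulus clones stood at 3.68 ± 1.56 (n = 5), close to cumulus clones at 3.76 ± 0.95 (n = 7). The Xist-KO cumulus donors carried the deletion on 1 X chromosome, so the other copy could be transcribed, and the level does not check the label there. Whether each of the 4 Xist probes lies inside the deleted part is not given in the sources used here, although the probe used was well above background in only 1 of 4 Xist-KO Sertoli clones. TSA clones had 5.08 ± 0.86 (n = 3), fibroblast clones 3.22 ± 1.12 (n = 8), B6x129 Sertoli clones 1.81 ± 1.04 (n = 4) and B6x129 male IVF embryos -6.32 ± 0.56 (n = 3).

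Female IVF embryos had Xist at 2.74 ± 1.35 (n = 6) and male IVF embryos at -4.23 ± 4.09 (n = 6). The wide spread among males came from the library labelled male IVF 9, which had Xist at 3.79 and the Y-linked genes Ddx3y at -6.64 and Eif2s3y at -6.43. The library labelled female IVF 10 had Ddx3y at 2.52 and Eif2s3y at 4.38, with Xist at 0.65. Both libraries stayed under their labels. Every comparison below with BDF1 IVF embryos therefore includes a library whose genes contradict its label, and counts without both are given.

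**Figure D1:**
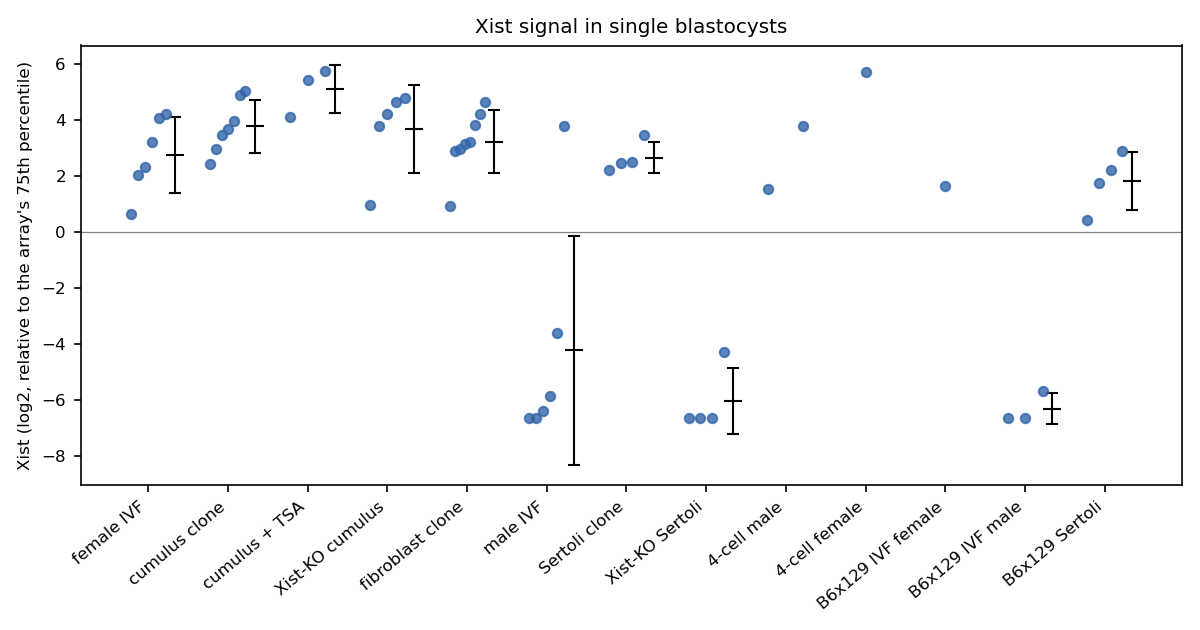
Level of Xist in each embryo by group (dots, log2 relative to the 75th percentile of the array), with mean ± SD for groups of 3 or more. The Xist-KO Sertoli clones lie between -6.64 and -4.28, and the Sertoli clones between 2.19 and 3.47.

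The X chromosome as a whole was summarised by the X index, the median level of X-linked genes minus that of autosomal genes in the same embryo. It was -0.486 ± 0.135 in female IVF embryos (n = 6) and -0.63 ± 0.197 in male IVF embryos (n = 6). It was -1.665 ± 0.577 in cumulus clones (n = 7), -3.405 ± 0.288 in Sertoli clones (n = 4) and -1.522 ± 0.993 in fibroblast clones (n = 8). In clones of Xist-KO cells it was -0.347 ± 0.186 for cumulus (n = 5) and -0.819 ± 0.232 for Sertoli cells (n = 4). TSA clones had -1.406 ± 0.659 (n = 3), B6x129 Sertoli clones -2.218 ± 0.841 (n = 4) and B6x129 male IVF embryos -0.879 ± 0.34 (n = 3).

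**Figure D2:**
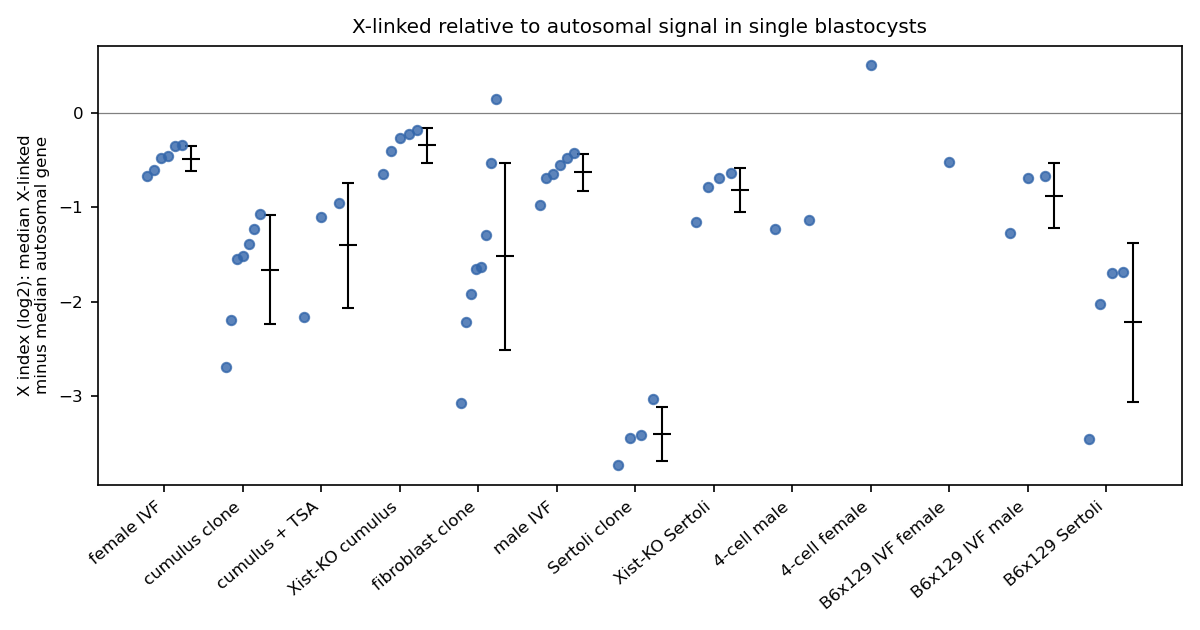
X index of each embryo by group (dots, log2), with mean ± SD for groups of 3 or more. The Sertoli clones average -3.405 and the Xist-KO Sertoli clones -0.819, next to -0.63 for male IVF embryos.

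Cumulus clones were set against female IVF embryos to ask what cloning of a female somatic cell changed. X-linked genes were lower in the clones: the X shift was -1.18, all 7 clones lay below every IVF embryo, and 73.9% of 559 X-linked genes had a value below 0 (exact two-sided permutation p = 0.00117, adjusted p = 0.0063). In all 536 genes changed, 169 higher and 367 lower, with 52 X-linked genes lower and 2 higher. The genes that fell furthest were germline genes of the X. Xlr3c fell by 8.84 ± 1.45 log2 (SE, adjusted p = 0.000143) and Xlr4b by 8.59 ± 1.33, members of a cluster best known for meiotic and imprinted expression. Of 5 Xlr genes measured 4 fell, and 5 fell when adjusted over the list alone, given below as within the list. The list median was -6.62 (camera adjusted p = 1.07e-10).

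Of 15 members of the Mage family, which encode antigens of germ cells and tumours, 5 fell and 0 rose, with 11 lower when within the list (median -1.86, camera adjusted p = 8.9e-13). Magea1 was at least 278-fold lower (limma adjusted p = 4.25e-06), Magea8 at least 242-fold and Magea6 at least 163-fold, while Magea3 fell by 7.78 ± 1.02 log2 and Magea5 by 5.17 ± 0.67. Other germline genes, some of them X-linked, went the same way. Of 33 measured, 9 fell and 0 rose (12 lower within the list), with a median of -0.94 (adjusted p = 3.64e-10). Asz1, which protects germ cells from transposons, was at least 170-fold lower (adjusted p = 1.57e-07), and Syce1, of the synaptonemal complex, fell by 5.85 ± 0.92 log2. Stk31 fell by 2.77 ± 0.45 and the meiotic cohesin Stag3 by 2.31 ± 0.41. The Xlr, Mage and germline calls held with an estimated correlation (adjusted p = 0.00358, 0.00358 and 0.00167).

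Primitive endoderm genes were lower as a group: 4 of 26 fell (15 within the list), with a median of -1.63 (adjusted p = 2.44e-08, and 0.0711 with an estimated correlation). Cubn, an endocytic receptor of the visceral endoderm, fell by 4.43 ± 0.68 log2 (adjusted p = 4.53e-05) and the transcription factor Foxa2 by 5.90 ± 1.38 (adjusted p = 0.0104). Bmp4, a signal from the early embryo to its surroundings, fell by 2.71 ± 0.62 (adjusted p = 0.00868). Chromatin genes had 3 falls among 39 (6 within the list). The list median was -0.29, and -0.02 with median centring and 0.03 in the value table (adjusted p = 0.0052, and 0.0433 with an estimated correlation). Cbx2, a subunit of the Polycomb complex, fell by 1.97 ± 0.26 log2 (adjusted p = 5.7e-06), and Dnmt3b, a DNA methyltransferase, by 1.15 ± 0.24 (adjusted p = 0.0041). The Dnmt3b call ended with median centring and in the value table.

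The genes that rose most were the natural killer cell receptor genes Klra7 (5.50 ± 0.83 log2, adjusted p = 4.18e-05), Klra4 (5.32 ± 0.66, adjusted p = 2.52e-06) and Klra16 (4.79 ± 0.75), which are neighbours. Cholesterol synthesis genes were higher as a group, with 3 of 24 risen and 0 fallen (11 risen within the list) and a median of 0.68 (adjusted p = 1.1e-10, and 0.128 with an estimated correlation). Msmo1 rose by 1.51 ± 0.36 and Tm7sf2 by 1.92 ± 0.46, both enzymes of the late pathway. Both calls ended when only the arrays compared were fitted. The p53 targets had a median of 0.28 with 1 of 28 risen (adjusted p = 0.0132, and 0.51 with an estimated correlation). Cell cycle genes had a median of -0.14, or 0.14 with median centring and 0.22 in the value table, and 0 of 34 passed (adjusted p = 0.0272, and 0.556 with an estimated correlation).

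The other lists did not pass as groups in cumulus clones. Among them were trophectoderm (1 of 39 risen, 2 fallen, adjusted p = 0.104), pluripotency genes (0 of 31 changed, adjusted p = 0.0519), zygotic genome activation (0 of 12, adjusted p = 0.105) and Y-linked genes (0 of 9, adjusted p = 0.0553). FGF, BMP and Wnt signalling had 1 fall among 28 (adjusted p = 0.233), fibroblast markers 3 among 29 (adjusted p = 0.44), Sertoli cell markers 1 among 23 (adjusted p = 0.841) and paternally expressed imprinted genes 1 among 31 (adjusted p = 0.818). Genes that escape X inactivation had 1 fall among 12, and the X-inactivation centre 1 among 9, the testis gene Tsx, which fell by 1.84 ± 0.40 log2 (both lists adjusted p = 0.603). Cumulus markers (18 measured, adjusted p = 0.313), the Rhox cluster (7, 0.603), placental genes (13, 0.643), housekeeping genes (14, 0.643), maternally expressed imprinted genes (27, 0.643), heat shock genes (23, 0.643), oocyte transcripts (20, 0.673), oxidative phosphorylation (50, 0.841) and glycolysis (20, 0.925) had no member that passed. Xist itself stood 1.01 ± 0.96 log2 higher (adjusted p = 0.703), with 2 of its 4 probes of the opposite sign.

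With scan campaign as a block 643 genes passed, and the X shift stratified by campaign was -1.19 (exact permutation p = 0.00286). Within campaign 1 it was -1.07 (p = 0.0571, smallest possible 0.0286, 107 genes) and within campaign 5 it was -1.33 (p = 0.1, the smallest possible, 100 genes), by exact two-sided permutation. Blocked medians were -6.60 for the Xlr, -1.85 for the Mage, -0.87 for the germline, -1.71 for the primitive endoderm, 0.64 for the cholesterol, -0.31 for the chromatin, 0.31 for the p53 and -0.14 for the cell cycle list. In campaigns 1 and 5 they were -6.70 and -6.47, -1.72 and -1.98, -0.72 and -1.10, -0.77 and -1.81, 0.94 and 0.40, -0.15 and -0.33, 0.58 and 0.16, and -0.03 and -0.26, in the same order. The balance of rises and falls depended on the scaling: median centring, which moved the median of all genes from -0.045 to 0.218 (below, the median is in brackets), gave 434 higher and 237 lower, and the value table (0.274) 553 and 256. Without the libraries labelled male IVF 9 and female IVF 10, 506 genes passed and the X shift was -1.217.

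Sertoli clones were set against male IVF embryos, where the only X is the active one. The fall of X-linked genes was the largest of any comparison: the X shift was -2.78, all 4 clones lay below every IVF embryo, and 88.4% of X-linked genes had values below 0 (exact two-sided permutation p = 0.00476, the smallest possible, adjusted p = 0.0143). Of 3193 genes that changed, 947 were higher and 2246 lower, with 259 X-linked genes lower and 5 higher. Xist rose by 6.88 ± 1.12 log2 (adjusted p = 3.33e-05). The fit of the arrays compared alone ended this call, and the controls included the library labelled male IVF 9 with its Xist. Genes of the X for metabolic and repair enzymes were among those that fell. The glycolytic enzyme Pgk1 fell by 7.30 ± 0.90 log2 (adjusted p = 2.36e-07), the mitochondrial dehydrogenase Hsd17b10 by 3.92 ± 0.45, the repair nuclease Apex2 by 5.46 ± 0.66, the sterol enzyme Nsdhl by 3.13 ± 0.55 and the respiratory subunit Cox7b by 1.89 ± 0.38.

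Further X-linked falls were Rnf128, a ubiquitin ligase (8.48 ± 0.85 log2, adjusted p = 1.17e-09), Mospd2 (5.65 ± 0.59) and Plac1, needed in the placenta (6.99 ± 1.22). Kdm5c, a histone demethylase that escapes silencing in female cells, fell by 1.36 ± 0.27. Escape genes as a list had 5 falls and 0 rises among 12 (5 within the list, camera adjusted p = 0.0545). Of 15 Mage genes 11 fell (11 within the list, median -4.96, adjusted p = 6.4e-09, and 0.0338 with an estimated correlation), with Magea8 at least 288-fold and Magea1 at least 265-fold lower. Of 5 Xlr genes 4 fell (4 within the list, median -5.45, adjusted p = 0.0033, and 0.329 with an estimated correlation), led by Xlr3c at -9.11 ± 1.68. Rhox5, an X-linked homeobox gene of the placenta and testis, rose by 4.68 ± 1.20 (adjusted p = 0.00549).

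The renin gene Ren1, on an autosome, fell by 9.47 ± 0.48 log2 (adjusted p = 1.34e-19). It stood at -6.17 ± 0.95 (SD, n = 4) against 3.31 ± 0.35 (n = 6) in male IVF embryos and 3.27 ± 0.78 (n = 7) in cumulus clones. Pdxdc1, a decarboxylase gene, fell by 8.55 ± 0.21 log2, and its other probe disagreed in sign. Neurofilament Nefl was at least 381-fold lower. Of 26 primitive endoderm genes 16 fell and 1 rose (20 and 1 within the list), with a median of -2.42 (adjusted p = 1.91e-05, and 0.329 with an estimated correlation). Fn1, encoding fibronectin, fell by 3.55 ± 0.68, Cubn by 3.81 ± 0.79 and the collagen chaperone Serpinh1 by 3.01 ± 0.63. Chromatin genes had 16 falls and 1 rise among 39 (17 and 1 within the list), with a median of -0.52 (adjusted p = 0.00181, and 0.0338 with an estimated correlation). The deacetylase Hdac1 fell by 1.65 ± 0.23, Dnmt3b by 1.82 ± 0.28 and the Polycomb subunit Cbx7 by 3.88 ± 0.53.

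Among trophectoderm genes 10 fell and 2 rose of 39 (adjusted p = 0.0982), among them Elf5, a regulator of trophoblast stem cells (-3.88 ± 0.90 log2). Of 28 signalling genes 10 fell and 1 rose (adjusted p = 0.0545), with Bmp4 at -3.92 ± 0.72 and the FGF antagonist Spry1 at -2.46 ± 0.48. Of 33 germline genes 9 fell and 2 rose (adjusted p = 0.0676), with Asz1 at least 116-fold lower, Dazl at -4.87 ± 0.99 and Dnmt3l at -1.48 ± 0.25. Pluripotency genes went both ways, 7 falling and 2 rising of 31 (adjusted p = 0.296). Nanog rose by 2.09 ± 0.43, and the LIF receptor Lifr fell by 3.92 ± 0.96. The p53 targets had 5 rises and 2 falls among 28 (6 and 2 within the list, median 0.39, adjusted p = 0.00709, and 0.353 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 2.77 ± 0.68 and Btg2 by 1.86 ± 0.36, while Trp53 itself fell by 1.60 ± 0.28. Other rises were Hspa1a, a heat shock protein (5.94 ± 1.38, 1 of 4 probes opposite), Hspb1, a small one (2.82 ± 0.54), Txnip, a brake on glucose uptake (5.76 ± 1.15) and Cidea, a lipid droplet protein (5.22 ± 0.59). Paternally expressed imprinted genes had 5 falls and 2 rises among 31 (adjusted p = 0.916).

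The Sertoli clones filled a slide of a campaign without IVF embryos, so slide, donor genotype and group cannot be told apart. With a random slide block 1376 genes passed. The median of all genes was -0.16. Scaling again set the balance: median centring (0.209) gave 1918 higher and 833 lower, the value table (0.378) 2450 and 818, and normexp 1159 and 1696. Without the libraries in doubt 3019 genes passed, with an X shift of -2.735.

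Fibroblast clones, made from another cell type, were also set against female IVF embryos. X-linked genes were lower on average but unequally: the X shift was -1.04, with 6 of 8 clones below every IVF embryo and clone 4, described below, above them all (exact two-sided permutation p = 0.0226, adjusted p = 0.0477). It did not pass in the value table (-0.329), with the strict filter (-0.637) or as a mean over genes (-0.519). In all 375 genes changed, 111 higher and 264 lower, with 26 X-linked genes lower and 2 higher. The natural killer receptor genes rose again, Klra4 by 6.12 ± 0.64 log2 (adjusted p = 6.11e-08), Klra7 by 6.14 ± 0.81 and Klra16 by 5.53 ± 0.73. Tbx18, a mesenchymal transcription factor, was at least 35.5-fold higher, and the placental hormone gene Prl8a9 rose by 4.76 ± 1.03. Asz1 fell by 5.94 ± 0.78, Foxa2 by 6.18 ± 1.34 and the endoderm factor Sox7 by 5.41 ± 1.22.

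Of 15 Mage genes 5 fell (9 within the list, median -1.75, adjusted p = 8.25e-09, and 0.0451 with an estimated correlation), with Magea1 at -5.06 ± 1.03 log2 and Magea5 at -3.27 ± 0.65. Of 33 germline genes 3 fell (10 within the list, median -0.86, adjusted p = 3.1e-05, and 0.0451 with an estimated correlation). Xlr genes had 3 falls of 5 (4 within the list, median -4.69, adjusted p = 2.79e-05, and 0.0648 with an estimated correlation). Primitive endoderm genes had 4 of 26 (11 within the list, median -0.99, adjusted p = 4.62e-06, and 0.16 with an estimated correlation), among them Serpinh1 (-2.16 ± 0.53) and Cubn (-2.47 ± 0.66). Chromatin genes had 4 of 39 (7 within the list, median -0.33, adjusted p = 0.0067, and 0.0648 with an estimated correlation), with Dnmt3b at -1.09 ± 0.23 and Kdm4b, a histone demethylase, at -1.60 ± 0.33.

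Paternally expressed imprinted genes had a median of -0.63 with 0 of 31 passing (2 falls within the list, adjusted p = 0.0333, and 0.264 with an estimated correlation). Without fibroblast clone 4 the median was -0.23 (adjusted p = 0.569). In that clone Slc38a4, an amino acid transporter gene of the placenta, lay at the floor of -6.64 and the signalling adaptor Gab1 at -5.25, against 5.29 ± 0.71 and 2.80 ± 0.76 (SD, n = 7) in the other fibroblast clones. Other lists that passed were p53 targets (median -0.44, adjusted p = 0.000969, and 0.264 with an estimated correlation), cholesterol synthesis (0.37, adjusted p = 0.00201, and 0.457), heat shock genes (-0.56, adjusted p = 0.0067, and 0.285), cell cycle (-0.25, adjusted p = 0.027, and 0.457) and glycolysis (-0.27, adjusted p = 0.0475, and 0.285), with at most 1 member passing in each. Without clone 4 the last 2 did not pass (adjusted p = 0.0766 and 0.0719).

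**Figure D3:**
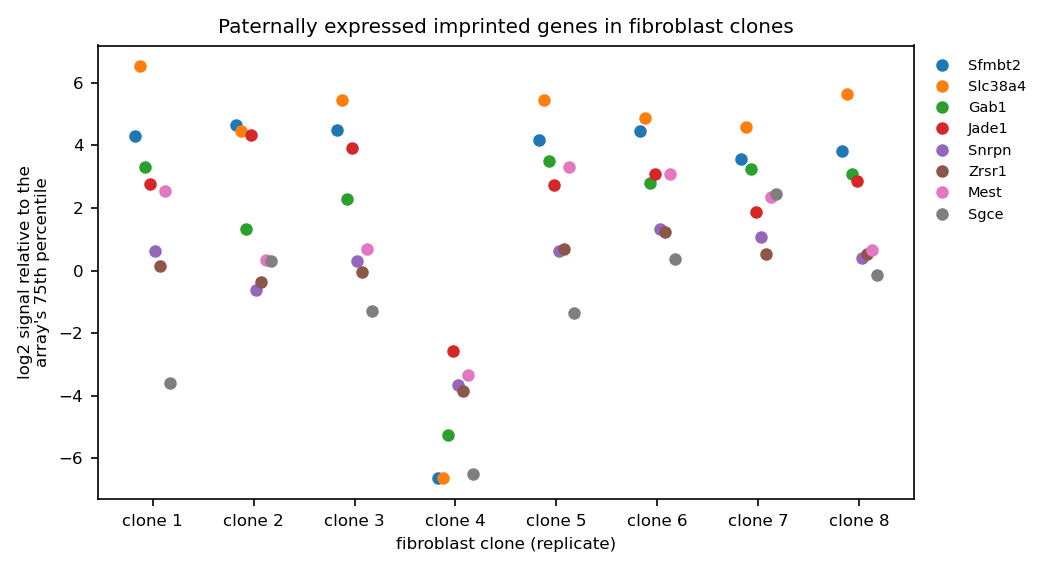
Levels of 8 paternally expressed imprinted genes in the 8 fibroblast clones (log2 relative to the 75th percentile of the array). In clone 4 Slc38a4 lies at -6.64 and Gab1 at -5.25, where the other clones average 5.29 and 2.80.

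A second scanner read 5 of the fibroblast clones. With campaign as a block 57 genes passed, Klra4 among them, and within campaign 5 the X shift was -0.66 (exact two-sided permutation p = 0.8, smallest possible 0.1, 7 genes), or -1.31 without clone 4, 1 of the 3 clones there. Blocked medians, and those within campaign 5, were -1.62 and -1.50 for Mage, -0.76 and -0.92 for germline, -2.14 and -2.11 for Xlr, -0.57 and -0.83 for primitive endoderm, -0.42 and -0.45 for chromatin, -0.90 and -0.72 for paternally expressed, -0.65 and -0.72 for p53, 0.50 and 0.43 for cholesterol, -0.09 and -0.07 for heat shock, -0.22 and -0.23 for cell cycle, and -0.02 and -0.02 for glycolysis genes. Blocked, the Xlr, chromatin, heat shock, cell cycle and glycolysis lists no longer passed (adjusted p = 0.11, 0.0705, 0.245, 0.105 and 0.872). Without fibroblast clone 4, 813 genes passed, and without the IVF libraries in doubt 306. Median centring (-0.125) gave 39 higher and 212 lower, and the value table gave 22 and 105.

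**Figure D4:**
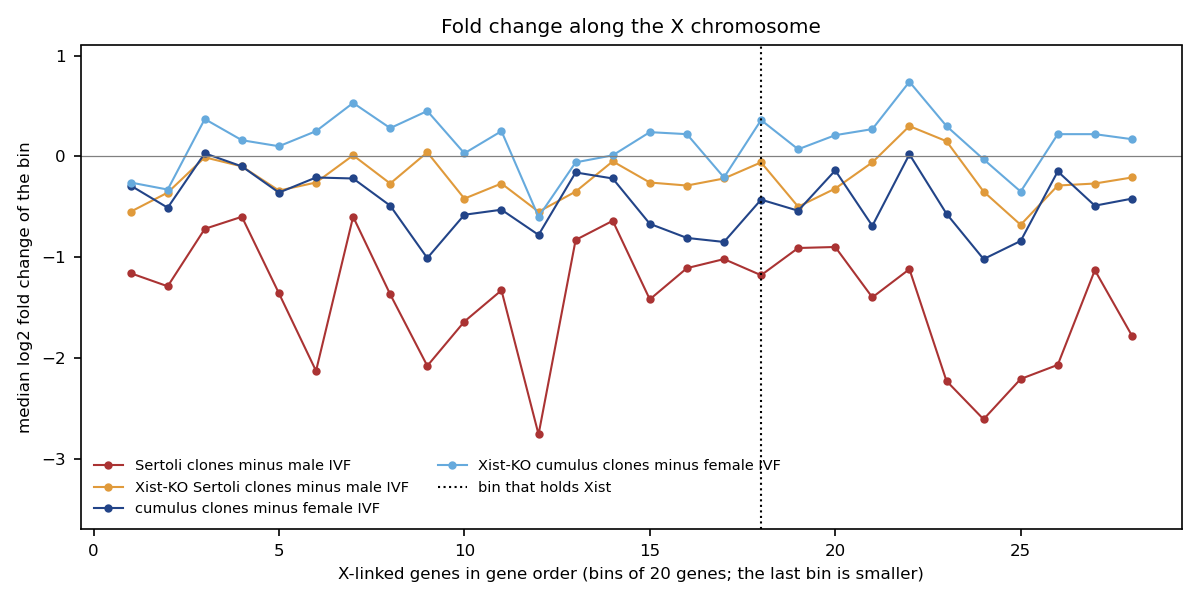
Median log2 difference of consecutive bins of 20 X-linked genes in chromosome order, for the clone comparisons. The dotted line marks bin 18 of 28, which holds Xist.

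Xist-KO cumulus clones, with the deletion on 1 X, were set against cumulus clones. X-linked genes were higher: the X shift was 1.32, and all 5 Xist-KO clones lay above every cumulus clone (exact two-sided permutation p = 0.00126, the smallest possible, adjusted p = 0.0063). Of 259 genes that changed, 94 were higher and 165 lower, and 31 X-linked genes rose while none fell by limma. Zfp275 rose by 4.12 ± 0.73 log2 (adjusted p = 0.00158), Fmr1nb, a testis antigen, by 4.09 ± 0.73 and Xlr by 4.81 ± 1.02 (adjusted p = 0.00757). Mageb4 rose by 3.81 ± 0.71, the ubiquitin ligase Pja1 by 3.30 ± 0.63, the transporter Xk by 2.18 ± 0.41 and the testis doublesex relative Dmrtc1c1 by 6.67 ± 1.46.

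Of 5 Xlr genes 2 rose (3 within the list, median 4.81, adjusted p = 2.82e-05, and 0.115 with an estimated correlation), Xlr4b by 5.60 ± 1.40, while Xlr3c stood 5.07 ± 1.52 higher without passing (adjusted p = 0.0847). Germline genes had 1 rise of 33 (4 within the list, median 0.75, adjusted p = 9.44e-05, and 0.115 with an estimated correlation). The Rhox cluster had 1 of 7 (1 within the list, median 2.41, adjusted p = 0.00339, and 0.24 with an estimated correlation), Rhox3a, at 3.02 ± 0.76. Mage genes had 1 of 15 (1 within the list, median 0.47, adjusted p = 0.0486, and 0.497 with an estimated correlation). Zygotic activation genes had 0 of 12 (2 within the list, median 0.72, adjusted p = 0.0111, and 0.336 with an estimated correlation).

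Lower in the Xist-KO clones were p53 targets, with 2 falls among 28 (2 within the list, median -0.50, adjusted p = 2.18e-05, and 0.161 with an estimated correlation). Phlda3, an inhibitor of Akt, fell by 2.18 ± 0.41 log2 (adjusted p = 0.00247). Mdm2, the ligase that degrades p53, fell by 1.16 ± 0.27, with probes that disagreed. Cholesterol synthesis genes had 0 passing (3 falls within the list, median -0.47, adjusted p = 0.000111, and 0.474 with an estimated correlation). Trophectoderm genes had 2 falls of 39 (2 within the list, median -0.17, adjusted p = 0.0138, and 0.474 with an estimated correlation), the galectin Lgals3 (-2.06 ± 0.37) and keratin Krt7 (-3.44 ± 0.76). Other falls were Notch3 (-3.68 ± 0.91), semaphorin Sema3b (-2.69 ± 0.45) and the olfactory receptor Olfr1153 (-3.08 ± 0.42). Snai2, a factor of epithelial to mesenchymal transition, rose by 4.28 ± 0.84. Xist stood at a difference of -0.08 ± 1.01 (adjusted p = 1, 2 of 4 probes opposite).

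The Xist-KO cumulus clones made up campaign 4 alone. A random slide block left 71 genes and ended the Dmrtc1c1, Xlr4b, Rhox3a and Notch3 calls among others. Median centring (-0.324) gave 84 higher and 1056 lower, the value table (-0.292) 122 and 1051, and quantile normalization 93 and 296.

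Xist-KO Sertoli clones were set against Sertoli clones, the same deletion in a cell with a single X. X-linked genes were higher by an X shift of 2.59, in 4 of 4 clones (exact two-sided permutation p = 0.0286, the smallest possible, adjusted p = 0.0477). Of 619 genes 412 were higher and 207 lower, and 149 X-linked genes rose while 1, Xist, fell, by 8.70 ± 1.23 log2 (adjusted p = 7.52e-06). Pgk1 rose by 6.28 ± 0.99 (adjusted p = 6.07e-05), Tmsb4x, encoding an actin-binding thymosin, by 6.15 ± 0.77, Rnf128 by 7.32 ± 0.93 and Nsdhl by 2.64 ± 0.60 (1 of 4 probes opposite). Bex1 was at least 318-fold and Nudt11, a phosphatase gene, at least 411-fold higher, both not well above background in Sertoli clones.

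Of 15 Mage genes 2 rose (5 within the list, median 1.63, adjusted p = 0.000161, and 0.213 with an estimated correlation), Maged1 by 5.13 ± 1.12 log2 and Mageb16 by 3.75 ± 0.90, while Magea3 stood 3.61 ± 1.29 higher without passing (adjusted p = 0.133). Escape genes had 1 rise of 12 (5 within the list, median 0.61, adjusted p = 0.00358, and 0.213 with an estimated correlation). Of the X-inactivation centre, Rlim, whose product activates Xist, rose by 1.85 ± 0.43. Primitive endoderm genes had 2 rises of 26 (3 within the list, median 1.43, adjusted p = 0.000161, and 0.242 with an estimated correlation), Cubn by 3.24 ± 0.86 and the proteoglycan Srgn by 4.97 ± 1.44. Germline genes had 2 of 33 (8 rises and 1 fall within the list, median 0.84, adjusted p = 0.000876, and 0.213 with an estimated correlation). Both, Nxf2 at least 24.6-fold and Taf7l at least 12.9-fold higher, are X-linked testis genes.

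Sertoli markers had 3 rises of 23 (5 and 1 fall within the list, adjusted p = 0.0206, and 0.234 with an estimated correlation). Chromatin genes had 2 of 39 (5 within the list, adjusted p = 0.0299, and 0.213 with an estimated correlation), including Hdac1 at 1.53 ± 0.26. Signalling genes had 2 of 28 and the Rhox cluster 0 of 7 (4 and 0 within the list, both adjusted p = 0.0299, and 0.353 with an estimated correlation). The p53 list had a median of -0.42 with 0 of 28 passing (adjusted p = 0.0185, and 0.454 with an estimated correlation). On autosomes Ren1 rose by 9.40 ± 0.52, its neighbour Ren2 by 7.57 ± 0.57, Pdxdc1 by 8.39 ± 0.23 (its other probe opposite) and the sialyltransferase St6galnac4 by 7.72 ± 0.44. All 4 of these stood near the floor in Sertoli clones but not in other BDF1 groups, and Pdxdc1 and St6galnac4 were also low in B6x129 Sertoli clones, at -6.64 ± 0 and -6.21 ± 0.87 (SD, n = 4). Each group had its own slide, so slide, donor genotype and deletion cannot be told apart. A random slide block left 136 genes, and the arrays compared alone 112.

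Genes called in odd-numbered clones were measured in others, which cannot part deletion from slide, campaign or donor genotype. Of 804 genes lower in Sertoli clones than in male IVF embryos, 695 (86.4%) were higher in Xist-KO Sertoli clones, by a median of 0.90 log2, which left them at -0.85 against IVF. The 159 X-linked genes among them moved by 2.42, 158 upwards, and the 571 autosomal genes by 0.61, 475 upwards. Of 149 genes lower in cumulus clones than in female IVF embryos, 112 (75.2%) were higher in Xist-KO cumulus clones, by 0.62, with 21 X-linked genes at 2.05 (20 upwards) and 111 autosomal genes at 0.45 (79 upwards). Of genes called higher, 296 of 395 in Sertoli and 35 of 54 in cumulus clones moved down, by medians of -0.58 and -0.26. With even-numbered clones the shares of lower genes were 78.7% of 1363 and 84.7% of 98.

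Against female IVF embryos, Xist-KO cumulus clones still differed in 674 genes, 250 higher and 424 lower, and the X shift was 0.14 (exact two-sided permutation p = 0.18, adjusted p = 0.245). It passed with the strict filter (0.324), in the value table (0.22) and without clone 2 (0.213). Mage genes stayed low: 6 of 15 fell and 1 rose (6 and 1 within the list, median -1.23, adjusted p = 1.41e-05, and 0.137 with an estimated correlation). Magea1 fell by 6.64 ± 1.16 log2 (adjusted p = 0.000628), Magea6 by 6.40 ± 1.02 and Magea3 by 6.16 ± 1.11. Asz1 fell by 6.28 ± 0.87 and Cbx2 by 1.93 ± 0.29, Cbx7 by 2.82 ± 0.49. Primitive endoderm genes had 5 falls of 26 (10 falls and 1 rise within the list, median -1.76, adjusted p = 5.66e-05, and 0.327 with an estimated correlation), with the laminin Lama1 at -3.71 ± 0.91 and the collagen Col4a1 at -1.91 ± 0.50. Chromatin genes had 4 of 39 (7 and 1 rise within the list, median -0.33, adjusted p = 0.0279, and 0.137 with an estimated correlation). Zygotic activation genes had 2 rises of 12 (7 within the list, median 1.75, adjusted p = 0.000125, and 0.137 with an estimated correlation), Sp110 by 1.74 ± 0.45 and Tdpoz1 by 2.92 ± 0.81. Klra7 rose by 5.52 ± 0.91, Klra4 by 5.05 ± 0.72 and the cytokine Ifng by 5.23 ± 1.41, while Igf2, an imprinted growth factor, fell by 2.01 ± 0.53. Median centring gave 91 higher and 310 lower, and the value table gave 69 and 226. A random slide block left 184 genes, leaving out clone 4 left 264, and without the libraries in doubt 607 passed.

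Against male IVF embryos, Xist-KO Sertoli clones differed in 858 genes, 228 higher and 630 lower, with an X shift of -0.19 (exact two-sided permutation p = 0.21, adjusted p = 0.262). Mage genes had 6 falls of 15 (7 within the list, median -0.98, adjusted p = 0.000816, and 0.603 with an estimated correlation), with Magea5 at -4.21 ± 0.78 log2 and Magea6 at -5.81 ± 1.09. This was the single list that passed. Rhox5 rose by 5.67 ± 1.20 (adjusted p = 0.00418) and Klra7 by 5.90 ± 0.97. Asz1 was at least 116-fold and the neural acetyltransferase Nat8l at least 103-fold lower. Nefl fell by 8.33 ± 1.30, Krt7 by 4.26 ± 0.84 and the pluripotency RNA-binding gene Lin28a by 2.11 ± 0.37. Xist differed by -1.83 ± 1.12 (adjusted p = 0.39), mostly through the library labelled male IVF 9 (mean of the other males -5.83). Median centring gave 547 higher and 136 lower genes and the value table gave 964 and 140 (medians of all genes 0.204 and 0.347), normexp 300 and 411 and quantile normalization 259 and 385. A random slide block left 107 genes. Without the libraries in doubt 858 passed, with an X shift of -0.149.

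TSA treatment of cumulus clones was compared with no treatment, to ask whether an inhibitor of histone deacetylases acts like the deletion. By limma 0 genes passed, with 2185 at a raw p below 0.05. The X shift was 0.26 (exact two-sided permutation p = 0.55, adjusted p = 0.635). Kantr, a noncoding RNA of the X, stood 3.44 ± 0.74 log2 higher without passing (adjusted p = 0.0564), and Xist stood 1.32 ± 1.20 higher (adjusted p = 0.756, 1 of 4 probes opposite). Lists with a shift but 0 members passing were oxidative phosphorylation (median -0.35, adjusted p = 0.00172, and 0.878 with an estimated correlation), p53 targets (-0.41, adjusted p = 0.0183, and 0.79) and signalling (0.23, adjusted p = 0.0496, and 0.79). Blocked by campaign their medians were -0.35, -0.31 and 0.15 (adjusted p = 0.00548, 0.397 and 0.397), and within campaign 1 -0.37, -0.35 and 0.13. The block called 62 genes, and campaign 1 alone 282 with an X shift of 0.14 (exact two-sided permutation p = 0.657). The TSA clones filled a slide of their own, so slide and treatment cannot be told apart. Median centring (-0.174) called 5 genes higher and 1 lower, quantile normalization 14 and 3, normexp 3 and 0, the value table gave 6 and 160, and array weights 124 and 298.

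Clones of 4-cell nuclei were set against all IVF embryos. The X shift over both sexes was -0.04 (permutation test, p = 0.888), but the male clones against male IVF embryos alone had -0.554 (exact two-sided permutation p = 0.0357), and the female clone had an X index of 0.5. In all 4172 genes changed, 1836 higher and 2336 lower. Genes of zygotic genome activation were high: 9 of 12 rose (9 within the list, median 4.08, adjusted p = 1.12e-09, and 0.00402 with an estimated correlation). Zfp352 rose by 5.39 ± 0.89 log2, Tcstv1 by 6.33 ± 1.13 and Tcstv3 by 5.30 ± 0.89, while Zscan4c, which marks the 2-cell stage, rose by 3.93 ± 0.65 but stood at -0.29 when the male clones alone were compared with male IVF. Genes of later lineages were low. Trophectoderm had 14 falls of 39 (19 and 1 rise within the list, median -0.60, adjusted p = 1.93e-06, and 0.107 with an estimated correlation), with keratin Krt8 at -2.05 ± 0.24. Primitive endoderm had 15 falls and 2 rises of 26 (18 and 2 within the list, median -2.83, adjusted p = 4.9e-06, and 0.219 with an estimated correlation), with Lama1 at -6.86 ± 0.98, Lamc1 at -2.76 ± 0.41 and Col4a1 at -3.57 ± 0.54.

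Glycolysis had 8 falls and 1 rise of 20 in the 4-cell clones (8 and 1 within the list, median -0.72, adjusted p = 0.00163, and 0.107 with an estimated correlation), Gapdh at -2.50 ± 0.29 log2 and Tpi1 at -2.41 ± 0.26. Oxidative phosphorylation had 12 falls and 1 rise of 50 (14 and 1 within the list, median -0.35, adjusted p = 0.00152, and 0.775 with an estimated correlation). Cholesterol synthesis had 6 falls of 24 (6 within the list, median -0.70, adjusted p = 0.00582, and 0.775 with an estimated correlation), with mevalonate kinase Mvk at -3.88 ± 0.49. The p53 targets had 6 rises and 1 fall of 28 (9 and 1 within the list, median 0.84, adjusted p = 0.00163, and 0.317 with an estimated correlation), Cdkn1a by 2.79 ± 0.69 and Ccng1 by 2.38 ± 0.45. Dppa3, a maternal factor that protects methylation, rose by 1.83 ± 0.32 and Tex19.1 by 1.91 ± 0.35, and the maintenance methyltransferase Dnmt1 fell by 2.14 ± 0.37. Xist rose by 5.56 ± 1.13, a call that ended with the campaign block, where the library labelled male IVF 9 is the single male control of that campaign.

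Blocked by campaign, 2649 genes passed in the 4-cell clones, and within campaign 5, 484 did, with an X shift of -0.17 (exact two-sided permutation p = 0.667, smallest possible 0.0833). Blocked and campaign 5 medians were 3.41 and 3.23 for zygotic activation, -0.62 and -0.81 for trophectoderm, -2.10 and -2.53 for primitive endoderm, -0.72 and -0.64 for glycolysis, -0.24 and -0.44 for oxidative phosphorylation, -0.39 and -0.85 for cholesterol (no longer passing, adjusted p = 0.1) and 0.40 and -0.03 for p53 genes. The 2 male clones and 1 female clone shared a slide, so slide and group are hard to part. Without male clone 1, 1926 genes passed, and without the IVF libraries in doubt 4445. Of 147 named genes, males alone kept 93, weakened 49 and reversed 4.

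In the B6x129 cross, Sertoli clones were set against male IVF embryos to ask whether the loss of X-linked expression depends on strain. The X shift was -1.34, in 4 of 4 clones (exact two-sided permutation p = 0.0286, the smallest possible, adjusted p = 0.0477). It did not pass in the value table (-0.835), with the strict filter (-1.197), as a mean over genes (-0.85) or without the Xlr, Mage, Rhox and inactivation centre genes (-1.291). Of 317 genes 127 were higher and 190 lower, with 26 X-linked genes lower and 2 higher, Xist and Rhox5. Xist was at least 280-fold higher (adjusted p = 0.000314) and Rhox5 rose by 8.61 ± 1.42 log2 (adjusted p = 0.000335). Asz1 was at least 158-fold lower, the transketolase relative Tktl1 at least 125-fold, and Hsd17b10 fell by 2.67 ± 0.53. Mage genes had 5 falls of 15 (6 within the list, median -2.21, adjusted p = 1.54e-06, and 0.215 with an estimated correlation), Magea6 at least 67.1-fold lower. Xlr genes had 2 of 5 (3 within the list, median -5.12, adjusted p = 0.000397, and 0.215 with an estimated correlation), Xlr3c at -8.41 ± 1.99. Germline genes had 2 of 33 (6 and 1 rise within the list, median -0.66, adjusted p = 0.00303, and 0.215 with an estimated correlation).

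Fibroblast markers in the B6x129 clones had 3 falls of 29 (4 within the list, median -0.89, adjusted p = 0.015, and 0.544 with an estimated correlation), Thy1 at least 54.1-fold, Timp2 at least 48.2-fold and Mmp2 at least 14.7-fold lower. Oxidative phosphorylation (median -0.34, but 0.05 with median centring and 0.02 in the value table) and cell cycle genes (median -0.35, but 0.04 and 0.01) had 0 members passing (adjusted p = 3.8e-05 and 0.00154, and 0.579 and 0.544 with an estimated correlation). Clones and embryos lay in different campaigns, so campaign and group cannot be told apart, and a random slide block left 44 genes. Median centring (0.287) gave 299 higher and 116 lower, and quantile normalization 249 and 184.

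Female and male IVF embryos differed in 7 genes, 5 higher and 2 lower in females. Xist was higher by 6.97 ± 1.0 log2 (adjusted p = 0.000272), and the Y-linked Ddx3y and Eif2s3y lower by -6.53 ± 1.14 and -6.64 ± 1.24. The others were Klhl10 (3.45 ± 0.67), Ankdd1b (3.08 ± 0.61), Cpm (2.48 ± 0.47) and the p53 target Btg2 (1.67 ± 0.32). The X shift was 0.15 (exact two-sided permutation p = 0.167, adjusted p = 0.245). Y-linked genes were lower as a list (2 of 9 fell, 6 within the list, median -3.33, adjusted p = 1.64e-12, and 0.00396 with an estimated correlation). Higher were p53 targets (1 of 28, with 8 rises and 1 fall within the list, median 0.71, adjusted p = 3.45e-08, and 0.0441 with an estimated correlation) and escape genes (0 of 12, 3 within the list, median 0.52, adjusted p = 0.000218, and 0.0441). Cholesterol genes were lower (median -0.70, adjusted p = 7.15e-08, and 0.271 with an estimated correlation) and germline genes higher (0.60, adjusted p = 0.00274, and 0.124), with 0 passing in either. Cell cycle genes (0.09, adjusted p = 0.00891, and 0.598) and the X-inactivation centre (0.19, adjusted p = 0.00955, and 0.0699) also passed.

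Both groups here held a library that contradicts its label, and without both 31 genes passed, with an X shift of 0.222 (exact two-sided permutation p = 0.0476). In the value table it was 0.165, also passing. Blocked medians, and those of campaign 1, were -3.23 and -5.17 for Y-linked, 0.50 and 0.42 for p53, 0.59 and 0.70 for escape, -0.60 and -0.47 for cholesterol, 0.23 and 0.23 for germline, 0.11 and 0.10 for cell cycle and 0.39 and 0.38 for X-inactivation centre genes. The block left 2 genes, and campaign 1 alone called 13 with an X shift of 0.19 (exact two-sided permutation p = 0.179).

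Fibroblast and cumulus clones were compared to see what the donor cell leaves behind. The X shift was 0.14 (exact two-sided permutation p = 0.745), and 688 genes differed, 229 higher and 459 lower in fibroblast clones. Of p53 targets 6 of 28 were lower (14 within the list, median -0.84, adjusted p = 1.79e-09, and 0.0599 with an estimated correlation), with Mdm2 at -1.24 ± 0.24 log2 (its other probe opposite) and Btg2 at -1.45 ± 0.29. The mean of probes ended both of these calls. Trophectoderm genes had 5 falls of 39 (9 within the list, median -0.36, adjusted p = 0.000299, and 0.373 with an estimated correlation), the trophoblast factor Tfap2c at -1.23 ± 0.18 and Lgals3 at -1.44 ± 0.33. Fibroblast markers had 2 rises of 29 (3 within the list, median 0.56, adjusted p = 0.0223, and 0.411 with an estimated correlation), Col5a2 by 3.44 ± 0.75 and Twist1 by 2.57 ± 0.69. Without fibroblast clone 4 the list had a median of 0.10 and did not pass (adjusted p = 0.397). Fam111a rose by 5.65 ± 0.89, Tbx18 by 4.79 ± 0.83, Cbx2 by 1.71 ± 0.24 (its other probe disagreed) and the germline gene Syce1 by 4.65 ± 0.85.

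Other lists passed between the cell types with a preset correlation only. They were heat shock (median -0.53, adjusted p = 0.00151, and 0.373 with an estimated correlation), cholesterol (-0.39, adjusted p = 0.00198, and 0.488), Xlr (1.80, adjusted p = 0.0167, and 0.401), and, all at adjusted p = 0.0477, glycolysis (-0.24, and 0.401), housekeeping (-0.32, and 0.401), germline (0.07, but -0.06 with quantile normalization and -0.31 with median centring, and 0.401) and Mage genes (0.27, but -0.06 with median centring, and 0.488). Without fibroblast clone 4 the Xlr (0.82), glycolysis (-0.30), germline (-0.02) and Mage (0.08) lists did not pass (adjusted p = 0.111, 0.0668, 0.17 and 0.355). Blocked and campaign 5 medians were -0.82 and -0.63 for p53, -0.13 and -0.17 for trophectoderm, 0.72 and 1.30 for fibroblast, -0.23 and 0.00 for heat shock, -0.25 and -0.06 for cholesterol, 4.18 and 3.54 for Xlr, 0.09 and -0.09 for glycolysis, 0.00 and 0.12 for housekeeping, 0.34 and 0.67 for germline and 1.14 and 1.19 for Mage genes. The block called 518 genes and campaign 5 alone 79, with an X shift of 0.67 (exact two-sided permutation p = 0.6), or 0.02 without fibroblast clone 4. Median centring (-0.332) gave 158 higher and 2435 lower, and the value table (-0.325) 345 and 2453.

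Effects were also compared between backgrounds. The deletion raised X-linked genes less in cumulus than in Sertoli clones, by -1.27 (permutation test, p = 0.00273, adjusted p = 0.0102), but in the value table by -0.278, not passing. In all 123 genes differed, 41 higher and 82 lower. Xist differed by 8.62 ± 1.59 log2, Ren1 by -9.62 ± 0.68, St6galnac4 by -7.67 ± 0.57, Ren2 by -7.76 ± 0.74, Erdr1, at the tip of the X, by -4.09 ± 0.64 and Hdac1 by -1.86 ± 0.33. Median centring (-0.361) gave 34 and 177, the value table (-0.299) 10 and 133. The primitive endoderm list alone passed (median -0.98, adjusted p = 0.023, and 0.667 with an estimated correlation).

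The X shift against IVF was smaller in size in cumulus than in Sertoli clones, by a difference of 1.60 (permutation test, p = 0.00009, adjusted p = 0.00135). In all 366 genes differed, 286 higher and 80 lower. Among them were Ren1 (9.37 ± 0.63 log2), St6galnac4 (7.87 ± 0.53), Rnf128 (7.49 ± 1.12) and Pgk1 (5.50 ± 1.19), with Xist at -5.86 ± 1.48. Cholesterol genes differed with 3 of 24 higher (15 within the list, median 1.36, adjusted p = 1.87e-09, and 0.523 with an estimated correlation), Nsdhl by 3.26 ± 0.73 and Cyp51 by 3.68 ± 0.93. Trophectoderm genes had 1 of 39 (8 higher and 1 lower within the list, median 0.59, adjusted p = 0.00719, and 0.523 with an estimated correlation). Median centring gave 95 and 67, normexp 194 and 108, and the value table gave 155 and 308. Without the libraries in doubt 320 genes passed.

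The X shift of Sertoli clones against male IVF embryos was lower in BDF1 than in B6x129, by -1.44 (permutation test, p = 0.00585, adjusted p = 0.0146). In the value table the difference was -0.25, not passing. In all 336 genes differed, 59 higher and 277 lower, and 336 without the libraries in doubt. Ren1 (-9.21 ± 0.74 log2), Mospd2 (-5.50 ± 0.92), Erdr1 (-3.82 ± 0.69) and Trp53 (-2.03 ± 0.46) were lower, and Septin4 (5.98 ± 1.40) and Tnfrsf13b (5.85 ± 1.34) higher. The primitive endoderm list had 0 of 26 passing (3 within the list, median -1.70, adjusted p = 0.000473, and 0.508 with an estimated correlation), chromatin genes 2 of 39 (median -0.56, adjusted p = 0.0211, and 0.278) and cell cycle genes 0 of 34 (median 0.21, adjusted p = 0.0211, and 0.699). The value table (0.163) gave 838 higher and 235 lower, and the median of all genes was -0.11. Slides differed between every group here.

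Lists of changed genes overlapped. Cumulus and Sertoli clones, with no shared controls, shared 61 higher and 200 lower genes against 7.84 and 40.4 for independent lists, with 2 opposite and a correlation across genes of 0.468 (genes are not independent replicates). Simulated groups without effect had little to call, so their 0 shared calls say nothing. Cumulus and fibroblast clones shared 31 higher and 88 lower genes (0.92 and 4.75 for independent lists, 0 opposite), or 5 and 4 with the controls split. The correlation was 0.551 (simulated 0.556) with a covariance of 0.309 (simulated 0.155). Cumulus and Xist-KO cumulus clones shared 58 and 127 (2.07 and 7.63, 0 opposite), or 8 and 22 split, with a correlation of 0.608 (simulated 0.495) and a covariance of 0.393 (simulated 0.154). Sertoli and Xist-KO Sertoli clones shared 113 and 426 (10.54 and 69.4, 4 opposite), or 16 and 83 split, with a correlation of 0.536 (simulated 0.401) and a covariance of 0.547 (simulated 0.155). Sertoli clones of the 2 crosses, without shared controls, shared 20 and 83 (5.89 and 20.9, 6 opposite), with a correlation of 0.319, and cumulus and 4-cell clones, with female IVF shared and no simulation, 49 and 97 (15.1 and 42.1, 20 opposite), with 0.257.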

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

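Tests chosen only after the result was seen are both tests on the IVF libraries, both on fibroblast clone 4, those of scan campaign, of the Xist deletion and of dim probes in fibroblast and B6x129 clones. Of 48 searches for a sample far from its group, 6 found one, and chance gives about 1 in 20 groups, or 2.4.

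A pair of IVF libraries had genes that contradict their labels. The library labelled male IVF 9 had Xist at 3.79 (next male -3.61) and a median of Y-linked genes of -6.64 (next male -2.68), and the library labelled female IVF 10 a Y-linked median of -0.768 (other females -6.64). Exchanged labels would put each library on the side of the other sex. All 5 Y-linked genes that part the other embryos by sex lay there in both. But Xist at 0.65 in the library labelled female IVF 10 lay with the females (3.16 ± 0.98, SD, n = 5), not the males (-5.83 ± 1.28, n = 5). RNA of a second embryo in the library labelled male IVF 9 would leave its own Y transcripts, and 0 of 5 were well above background. In that labelled female IVF 10 all 5 were, beside Xist. Mixing there and biological causes were not tested, and exchange or separate wrong labels stay open.

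Fibroblast clone 4 had some paternally expressed RNAs low and some maternally expressed ones high. The median of 31 paternally expressed genes lay -0.99 from the other fibroblast clones, below all of 10000 random lists matched on level (middle 95% of them -0.29 to 0.38), and 10 of them lay more than 2 log2 below every other clone. The 27 maternally expressed genes had a median of 0.56, at the 99.8th percentile of their own random lists. Poor amplification would lower detection, yet 59.7% of its probes were well above background (51.2 to 59.8% in the others). An embryo without a paternal genome, such as an activated oocyte that was not enucleated, may be a candidate explanation, but Igf2 (2.37), Impact (1.18) and Inpp5f (3.33) were not low, and its genotype was not tested.

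X-linked genes were lower in somatic cell clones. Scan campaign is argued against as the whole cause in cumulus clones, with a shift stratified by campaign of -1.19 (permutation p = 0.00286), and stays open in fibroblast clones (-0.661, not passing, and -1.31 without clone 4). A floor under dim probes is argued against in Sertoli clones by their shift with a strict filter, -2.498 (exact permutation p = 0.00476, the smallest it can give), and stays open in fibroblast (-0.637) and B6x129 clones (-1.197), which did not pass with it. Xist made from the donor's X may be the source, because Xist-KO Sertoli clones stood 2.586 above Sertoli clones, with 4 of 4 higher than every Sertoli clone. This coincides with slide and perhaps donor genotype, so Xist stays a hypothesis.

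Splits of the same samples into other groups tested chance, and the real count comes first, then the highest other split. Chance can be excluded for cumulus clones against IVF (1 of 100 splits as large, 536 and 265, the latter following scan campaigns 1 and 5), Sertoli clones against IVF (1 of 100, 3193 and 777), Xist-KO cumulus against cumulus clones (1 of 100, 259 and 21) and against IVF (1 of 100, 674 and 52), Xist-KO Sertoli clones against IVF (1 of 100, 858, the other at 15% of it), fibroblast against cumulus clones (1 of 100, 688 and 225) and the effect of cloning between cell types (1 of 100, 366 and 131). For fibroblast clones against IVF (1 of 100, 375 and 374) and B6x129 Sertoli clones (1 of 35, 317 and 306) the share alone excludes it, but with another split at 99.7 and 96.5% of the real count this is weak. It cannot be excluded for Xist-KO against plain Sertoli clones (4 of 35, 619 and 1557), where the split of Sertoli clone 1 and Xist-KO clones 1, 2 and 3 from the rest called 252% of the real count. Nor can it for female against male IVF (10 of 100, 7, the other at 1840% of it, a structure of the samples), the deletion between cell types (5 of 100, 123 and 347) and cloning between strains (5 of 100, 336 and 485). For TSA the count of 0 by limma (2185 at unadjusted p under 0.05) is reached by 100 of 100 splits by construction, so they say nothing, and the highest, 39, set cumulus clones 5, 6 and 7, all of campaign 5, apart (blocked fit 62).

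Xist in Xist-KO cumulus clone 3 was 0.971, against 3.79 or more in the others of its group. Xist in Xist-KO Sertoli clone 4 was -4.28, where the others were at -6.64. The median of paternally expressed genes in cumulus clone 1 was -2.73 (next -1.69). The X shift of Xist-KO against plain clones differed between cumulus and Sertoli cells by -1.268 (permutation p = 0.00273) with 123 genes. The X shift of clones against IVF differed by 1.596 between the cell types (permutation p = 0.00009) with 366 genes. It differed by -1.435 between strains (permutation p = 0.00585) with 336 genes. The single B6x129 female IVF embryo, in no comparison, had Xist at 1.65 (highest B6x129 male -5.67).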

How the results depend on the processing

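Added after seeing the data were other floors, single campaigns (also without fibroblast clone 4), the fit without both IVF libraries in doubt and that of the male 4-cell clones alone. Of 422 alternative counts of changed genes 321 stayed within 1.5 times the main count, and of 406 alternative X shifts 382 kept their direction and their side of the threshold. The cause of a change was not tested unless said. Dim genes limit what these arrays show, since only 51.2 to 61.1% of probes were well above background. In what follows, comparisons are named by clone, against IVF unless said.

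Quantile normalization gave 389 genes for Xist-KO cumulus against cumulus clones and 17 for TSA, and Dppa5a between fibroblast and cumulus clones 0.04. Normexp, run on the median spot signal because the files held no mean, gave 3 for TSA, and Dppa5a 0.01. Median centring gave 1140 for Xist-KO cumulus against cumulus, 401 for Xist-KO cumulus, 6 for TSA, 2593 for fibroblast against cumulus, 211 for the deletion between cell types, 162 for cloning between cell types and 184 between strains. The value table gave 809 for cumulus, 127 for fibroblast, 1173 for Xist-KO cumulus against cumulus, 328 for Xist-KO Sertoli against Sertoli, 295 for Xist-KO cumulus, 166 for TSA, 901 for B6x129, 32 for female against male IVF, 2798 for fibroblast against cumulus and 1073 between strains. Its X shifts were -0.329 for fibroblast, -0.835 for B6x129, -0.278 for the deletion between cell types and -0.25 between strains, none passing, and 0.22 for Xist-KO cumulus and 0.165 for female against male IVF, both passing.

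Without a filter TSA gave 2 genes, and with a floor of 0.02 it gave 3. The strict filter gave X shifts of -0.637 for fibroblast and -1.197 for B6x129, not passing, and 0.324 for Xist-KO cumulus, passing. The mean over genes gave -0.519 for fibroblast and -0.85 for B6x129, and X-linked genes without the families -1.291 for B6x129, not passing. The mean of probes turned Sfn in Sertoli clones to 0.58 and Lrp2 in Xist-KO cumulus clones to 0.04. A limit of 2-fold left 405 genes for fibroblast against cumulus. With only the arrays compared, and so fewer samples to estimate the spread, counts were 1855 for Sertoli, 45 for fibroblast, 112 for Xist-KO Sertoli against Sertoli, 250 for Xist-KO Sertoli, 45 for TSA, 77 for B6x129, 0 for female against male IVF by limma (1404 at unadjusted p under 0.05, and 32 with array weights), 321 for fibroblast against cumulus and 120 between strains. Array weights gave 945 for cumulus, 1821 for fibroblast, 1167 for Xist-KO cumulus against cumulus, 1832 for Xist-KO cumulus, 422 for TSA, 922 for B6x129, 32 for female against male IVF, 2123 for fibroblast against cumulus and 380 for the deletion between cell types.

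The campaign block gave 57 for fibroblast, 62 for TSA, 2649 for 4-cell and 2 for female against male IVF, with Atp5b in fibroblast clones at 0.05 and Krt18 against cumulus at 0.16, and campaign strata an X shift of -0.661 for fibroblast, not passing. A random slide block gave 355 for cumulus, 1376 for Sertoli, 84 for fibroblast, 71 for Xist-KO cumulus against cumulus, 136 for Xist-KO Sertoli against Sertoli, 184 for Xist-KO cumulus, 107 for Xist-KO Sertoli, 44 for B6x129, 1 for female against male IVF, 282 for fibroblast against cumulus, and 21, 96 and 64 for the differences between effects. Replicate numbers do not pair the samples: in no comparison did every same-numbered pair correlate above 0.1 (Sertoli against male IVF 0.035 to 0.087). With the replicate number as a block, 799 genes passed for fibroblast, 3 for TSA and 51 for cloning between cell types. Without both IVF libraries in doubt, female against male IVF gave 31 genes and an X shift of 0.222, passing. Male 4-cell clones alone gave 1010 genes and an X shift of -0.554, passing, with Rhox13 at -0.71, Shbg at -0.04, Fbln1 at 0.34 and Zscan4c at -0.29. With an estimated correlation 12 of 85 list calls held.

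Leaving out each embryo gave ranges of genes and X shift of 369 to 537 and -1.278 to -1.008 for cumulus, 2262 to 3061 and -2.9 to -2.667 for Sertoli and 423 to 836 and 2.478 to 2.712 for Xist-KO Sertoli against Sertoli. Fibroblast gave 161 to 813 and -1.275 to -0.814, with counts of 167, 181 and 191 without female IVF 5, 7 and 8, and 813, 221, 219, 188 and 161 without clones 4 to 8. Xist-KO cumulus against cumulus gave 146 (without Xist-KO clone 4) to 271 and 1.146 to 1.417. Xist-KO cumulus gave 264 to 758 and 0.098 to 0.213 (418, 408 and 426 without female IVF 5, 7 and 8, 264 without clone 4, and 0.213, passing, without clone 2). Xist-KO Sertoli gave 441 to 831 and -0.259 to -0.077 (441 and 570 without clones 1 and 2, and -0.259, passing, without male IVF 1). TSA gave 0 to 27 and 0.032 to 0.637 (1 and 2 without cumulus 2 and 4, and 7, 12 and 27 without TSA 1, 2 and 3). The 4-cell clones gave 1926 (without male 1) to 4401 and -0.087 to -0.012. B6x129 gave 1.3e2 to 457 and -1.536 to -0.926, where so few embryos cannot reach the threshold (181, 1.3e2 and 135 without IVF 2, 3 and 4, and 198 without clone 2). Female against male IVF gave 5 to 41 and 0.075 to 0.184 (11, 13 and 41 without males 2, 6 and 9, 11 without female 10 or 12). Fibroblast against cumulus gave 414 to 873 and -0.096 to 0.365 (448 without cumulus 4, 414 without fibroblast 6). The deletion between cell types gave 79 to 359 and -1.44 to -1.161 (189 without Sertoli 1, 79 and 359 without Xist-KO Sertoli 1 and 4), cloning between cell types 241 (without female IVF 12) to 463 and 1.488 to 1.767, and between strains 193 to 442 and -1.848 to -1.239 (193 and 201 without B6x129 IVF 2 and 4).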

Other observations

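Xist was present in male clones of early nuclei. Both male 4-cell clones had it, at 1.51 and 3.76, and the female one at 5.69, and their X indices were -1.14, -1.228 and 0.5. The library labelled female IVF 10 lay on the same slide as these 3. Rhox5 was high in Sertoli clones with and without Xist (6.52 ± 0.37 and 7.51 ± 0.25, SD, n = 4 each) and in B6x129 Sertoli clones (7.15 ± 0.62, n = 4), next to 1.84 ± 2.45 in male IVF embryos (n = 6). Ren1 was at -6.17 ± 0.95 in Sertoli clones (n = 4) and 3.23 ± 0.68 in Xist-KO Sertoli clones (n = 4), with its neighbours Ren2 at -5.96 ± 0.79 and 1.60 ± 0.65, and Etnk2 at -3.47 ± 0.68 and 0.49 ± 0.55. In all, 17 autosomal and 6 X-linked genes were lower in each Sertoli clone than in every other library, next to 13 and 0 for TSA, 4 and 0 for Xist-KO Sertoli and 2 and 0 for Xist-KO cumulus clones, and 3 and 0 for B6x129 male IVF.

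Tests of strain alleles and of Xist level against the X index were chosen after values were seen, and the test of distance was set before. Pdxdc1 and St6galnac4, low in the Sertoli clones described as BDF1, were low also in B6x129 IVF embryos. A candidate explanation is that these Sertoli donors lacked the DBA/2 alleles that the array probes detect. It was tested on 7 other autosomal genes, over 1 log2 lower in all 4 B6x129 IVF libraries than in all 12 BDF1 ones. The Sertoli clones were on the B6x129 side in 89.3% of values (85.7 to 100 per clone), B6x129 Sertoli clones in 82.1%, and the Xist-KO Sertoli clones in 14.3%, with at most 42.9% in any single library of another BDF1 clone group. Of 14 genes higher in B6x129 IVF embryos, Sertoli clones had 12.5% on that side and B6x129 Sertoli clones 65.5%. Ren1 was not low in B6x129 embryos, which decides nothing, since their other strain may supply it. The donors' genotype was not tested, and the 4 clones filled a slide. Differences between Sertoli clones and other BDF1 groups may therefore include donor genotype.

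If silencing weakened with distance from Xist, the fall in Sertoli clones would shrink along the chromosome. Across 557 X-linked genes, which are not independent replicates, the rank correlation was -0.018 (permutation p = 0.676), which argues against it. If more Xist meant less X-linked expression, both would correlate negatively across clones. The relation was computed in 2 groups. In 7 cumulus clones Pearson's r was -0.631 (exact permutation p = 0.126, adjusted p = 0.209) and Spearman's rho -0.714 (p = 0.0881, adjusted p = 0.176), and r without the 2 farthest clones was -0.003. In 8 fibroblast clones r was -0.496 (p = 0.209, adjusted p = 0.209) and rho -0.167 (p = 0.703, adjusted p = 0.703), and r without the 2 farthest was -0.038. Neither passed, and so few embryos do not decide it.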
